A study of Mus musculus with 11 samples.

How the data were processed

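Captured DNA of 11 mouse liver libraries was analysed, 6 of the inbred strain DBA/2J and 5 of C57BL/6J. The labels give each library a strain, a sex and an age in days. Ages of 107 and 108 days formed the young class, 308 to 345 days the mid class and 708 to 711 days the old class. The series names its classes by months of age, and the library of 308 days was placed in the mid class. The labels do not say that each library came from a separate animal, so the p-values refer to these libraries and not to animals.

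Per the labels' protocols, DNA was isolated with a column kit that also recovers RNA, sheared by ultrasound and enriched for methylated fragments with a methyl-CpG-binding domain (MBD) capture kit. Per the labels' protocols, the 11 barcoded libraries were multiplexed and sequenced over several Ion Proton chips. Per the submitters' processing notes, FastQC, Trimmomatic 0.30, SAMtools and edgeR were used, with the mouse builds mm10 and GRCm38. The aligner and its settings are not given in the sources used here.

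Per the file headers, the deposited counts are numbers of reads in bins of 500 bp from the MEDIPS package, and their values are whole numbers without normalization. Per the file headers, the deposited relative methylation score is normalized to CpG density by MEDIPS; its values run from 0 to 1 and are rounded to 2 decimals. The score is not a measured share of methylated cytosines. The deposited table held 466039 bins on the 19 autosomes and on chromosome M. Every bin had at least 3 CpGs, at least 40 reads over all libraries and at least 12 reads in 2 or more libraries, so bins below these values are not in the table. No bin on the sex chromosomes was analysed here. All columns of values matched a sample.

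Total reads per library lay between 6.89 and 8.54 M, with a median of 15 reads per bin and library. A bin with 15 reads carries a large counting error, and the median standard error of a log2 change was 0.354 for old against young and 0.315 for the strains. Intervals given for ratios of read sums are exact binomial intervals at 95 percent and cover counting error only. Neighbouring bins are not independent. Of all bins 52.9 percent had a neighbour directly after them, and the median correlation of such neighbours over libraries was 0.573.

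Bins were placed with GENCODE M21 on the mm10 build. The number of CpGs in the table equalled a count in the assembly for 98.2 percent of bins. Of the bins, 108845 overlapped an exon, 203463 lay in a gene body without exon and 153731 lay outside gene bodies. A bin was assigned to a gene if it overlapped the gene body or lay within 5 kb of its start, which placed 328489 bins. Promoters were the summed counts of the bins within 2 kb of a transcription start, and 12130 genes had a tested promoter.

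The tests were fixed before the data were examined. Counts were normalised by the trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood fit over all 11 libraries and terms for strain, sex and age class. The edgeR filter on low counts kept all 466039 bins. P-values were adjusted by Benjamini-Hochberg over all bins, at a threshold of 0.05. The strain by age interaction used age in days as a continuous term, and its coefficient is a difference of log2 slopes per 100 days. The common dispersion was 0.0367, a biological coefficient of variation of 19.2 percent. No dispersion was estimated for single bins, and the quasi-likelihood step had 4723 prior beside 6 residual degrees of freedom. The p-value of a bin therefore drew on spread pooled over bins and hardly on that bin's own spread between libraries. Levels are given as CPM (counts scaled to library size by TMM), as mean ± SD over libraries. The reported log2 changes come from the fit, which holds sex and strain fixed, and can differ from a plain ratio of group means.

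Genes were named by a rule fixed at the same time. For each age comparison and for strain, the bins past the threshold that lay in a named gene were ranked by p, and the first 12 in each direction were named, with 1 bin per gene. For strain, only bins with at least 1 read in every library could be named. Where fewer than 5 bins passed in a direction, the first 5 were named with their adjusted p, and the interaction and sex comparisons named 5 in each direction. Other bins past the threshold are named where a comparison had few of them, and these were chosen after their values were seen. Up to 4 members of each gene list with the smallest p, and the promoters of Hnf4a, Alb, Ezh2 and Elovl2, completed the rule; 2 list members that it names are not reported here. The promoters of Hnf4a, Ezh2 and Elovl2 had no tested value.

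The 16 gene lists were fixed together with the tests. They cover developmental transcription factors, clustered protocadherins, imprinted genes, hepatocyte proteins, xenobiotic metabolism, lipid metabolism, insulin and growth signalling, the circadian clock, senescence, tumour suppressors, polycomb and DNA methylation enzymes, the major histocompatibility complex, lymphocytes, Kupffer and myeloid cells, endothelial, stellate and bile duct cells, and major urinary proteins. Lists were tested on promoters with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The tests for the mid class were added after the data were seen.

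The fits were tested on simulated data with the dispersion set to 0.04 over 466039 bins. For old against young, 5 of 67 bins changed 2-fold were recovered, as were 31 of 67 changed 3-fold and 44 of 66 changed 4-fold, and 6 unchanged bins were called. A change of 2-fold in a single bin was therefore seldom detectable. All simulated bins had the same dispersion, so the 6 calls do not show how many arise where spread differs between bins. A simulated shift of 0.4 log2 in the circadian clock list was recovered for old against young, with a median of 0.597 log2 and no other list called among 11961 tested promoters. For the lists the dispersion was set lower than for the bins, and genes were drawn independently of each other. This check therefore does not cover lists whose members are correlated.

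The alternatives planned for old against young were DESeq2 size factors, library size alone, no filter, a mean of at least 20 reads, the DESeq2 1.42.0 Wald test, females alone, no sex term, age in days, autosomes alone, bins of 1 kb, the relative methylation score with limma and a pseudocount of 0.1, an offset by CpG number, and each library left out in turn. For the other comparisons a part of these was planned, and for strain also bins with at least 1 read in every library, for sex the DBA/2J libraries alone, and for the interaction age classes in females. Fitting without a filter gave nothing new, because the filter removed no bin. Added after the data were seen were bins outside exons, C57BL/6J libraries alone for old against young, at least 1 read in every library for the age and sex comparisons, and the CpG offset, score, 1 kb or other settings where a comparison had not listed them. Figures were drawn with matplotlib 3.10.9.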

Results

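DNA methylation was measured in liver of 2 inbred mouse strains, DBA/2J and C57BL/6J, at 3 ages. Fragments that carry methylated CpGs were captured with an MBD protein and sequenced, so the reads in a bin rise with its number of CpGs and with their methylation. The young class held 2 DBA/2J and 2 C57BL/6J females of 107 or 108 days. The mid class held 2 females and 1 male of DBA/2J, aged 341 or 345 days, and 1 C57BL/6J male of 308 days. The old class held 1 DBA/2J female of 708 days and 2 C57BL/6J females of 711 days. Total reads in the 466039 bins lay between 7.08 and 8.54 M in young, between 6.89 and 8.01 M in mid and between 8.07 and 8.42 M in old libraries.

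The 2 strains separated on the first principal component, which held 22.2 percent of the variance. C57BL/6J young replicate 2 lay apart from its strain there, at 57 beside 142.4 to 223.6 in the other C57BL/6J libraries. Its Spearman correlation with replicate 1 was 0.456, below the median of 0.532 for pairs from different strains. Libraries also differed in the capture of CpG-dense DNA. In bins with over 20 CpGs, the mean count relative to all bins of the same library was 1.21 in C57BL/6J young replicate 2 and 1.69 in replicate 1 of the same group. It was 2.16 in the C57BL/6J mid male and between 1.46 and 2.07 in the other libraries. Pairs of libraries of the same group differed by more than sampling noise, with a chi-square over degrees of freedom between 1.39 and 1.77, so no library was counted as a copy of another.

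**Figure D1:**
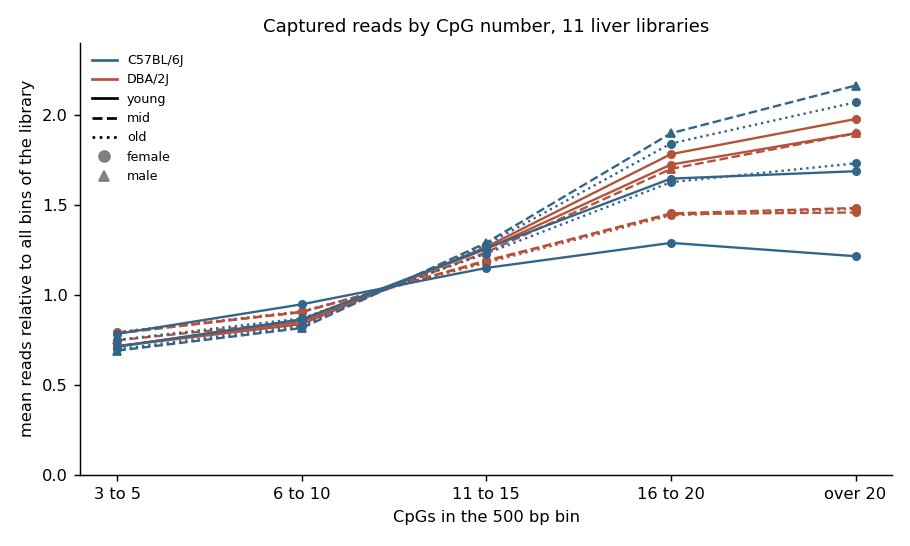
Mean reads per bin relative to all bins of the library (vertical axis) in 5 classes of CpG number (horizontal axis), 1 line per library. Colour gives the strain, line type the age class and marker the sex. In bins with over 20 CpGs the lines spread from 1.21 to 2.16.

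Old livers were compared with young ones to find regions whose captured methylation differed with age. Bins in 6 genes rose in old livers. C1ql3, which encodes a secreted protein of synapses, rose in a coding exon on chromosome 2 (13010001 to 13010500, 35 CpGs) from 0.331 ± 0.366 CPM in young (SD, n = 4) to 3.69 ± 0.881 in old livers (SD, n = 3). The log2 change was 3.30 (SE 0.447, edgeR adjusted p = 8.6e-08). Srd5a2, which encodes the steroid 5-alpha-reductase that makes dihydrotestosterone, had 1 read over all 4 young libraries in the bin at its transcription start on chromosome 17 (74047501 to 74048000, 31 CpGs). The 3 old libraries had 22, 25 and 16 reads there, a ratio of 77.8 with a counting interval from 13.5 to 3121 (edgeR adjusted p = 8.4e-07). The next bin of Srd5a2 in an intron (74047001 to 74047500) rose by 3.22 log2 (SE 0.522, adjusted p = 8.8e-05).

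Rfx4, a transcription factor of the RFX family, rose in a pair of intron bins on chromosome 10, by 3.17 log2 (SE 0.502, adjusted p = 4.9e-05) at 84760001 to 84760500 and by 4.08 log2 (SE 0.826, adjusted p = 0.0425) at 84759501 to 84760000, where the call was lost in 16 of 23 other settings. Ptk7, a receptor-like kinase of planar cell polarity, rose in an intron bin on chromosome 17 (46628501 to 46629000) from 0.713 ± 0.258 to 3.14 ± 0.267 CPM, a log2 change of 2.16 (SE 0.370, adjusted p = 5.7e-04). The bin of Ptk7 next to its transcription start (46629001 to 46629500, 59 CpGs) rose by 4.10 log2 (SE 0.75, adjusted p = 0.00377). Atp11a, a phospholipid flippase, rose by 1.90 log2 (SE 0.385) in a coding exon on chromosome 8 (12835001 to 12835500), and Lmln, a metallopeptidase, by 2.22 log2 (SE 0.453) in an intron on chromosome 16 (33122501 to 33123000). Both had an adjusted p of 0.0425, and Atp11a lost the call in 19 of 23 other settings and Lmln in 19 of 24.

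Bins in 2 genes fell. Ntpcr, a nucleoside triphosphatase, fell by 1.60 log2 (SE 0.327, adjusted p = 0.0425) in an exon with a 5 prime UTR on chromosome 8 (125738001 to 125738500), from 3.83 ± 0.418 to 1.295 ± 0.379 CPM, and lost the call in 19 of 23 other settings. Igfbp7, which encodes a binding protein for insulin-like growth factors, fell by 1.54 log2 (SE 0.301, adjusted p = 0.0198) in a coding exon on chromosome 5 (77351501 to 77352000). This value rested on C57BL/6J young replicate 2 with 128 reads, beside 7 to 11 reads in the other young libraries, and without it the log2 change was 0.74 (adjusted p = 0.812). Cep170b (log2 change -2.08, adjusted p = 0.0714), the homeobox gene Cux2 (-1.32, adjusted p = 0.180) and Fastk (-1.51, adjusted p = 0.207) did not pass. In total 9 bins were higher and 2 lower in old livers among 466039 tested. With C57BL/6J libraries alone, with a mean of at least 20 reads or with the relative methylation score no bin passed, and with the DESeq2 Wald test 2 did.

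**Figure D2:**
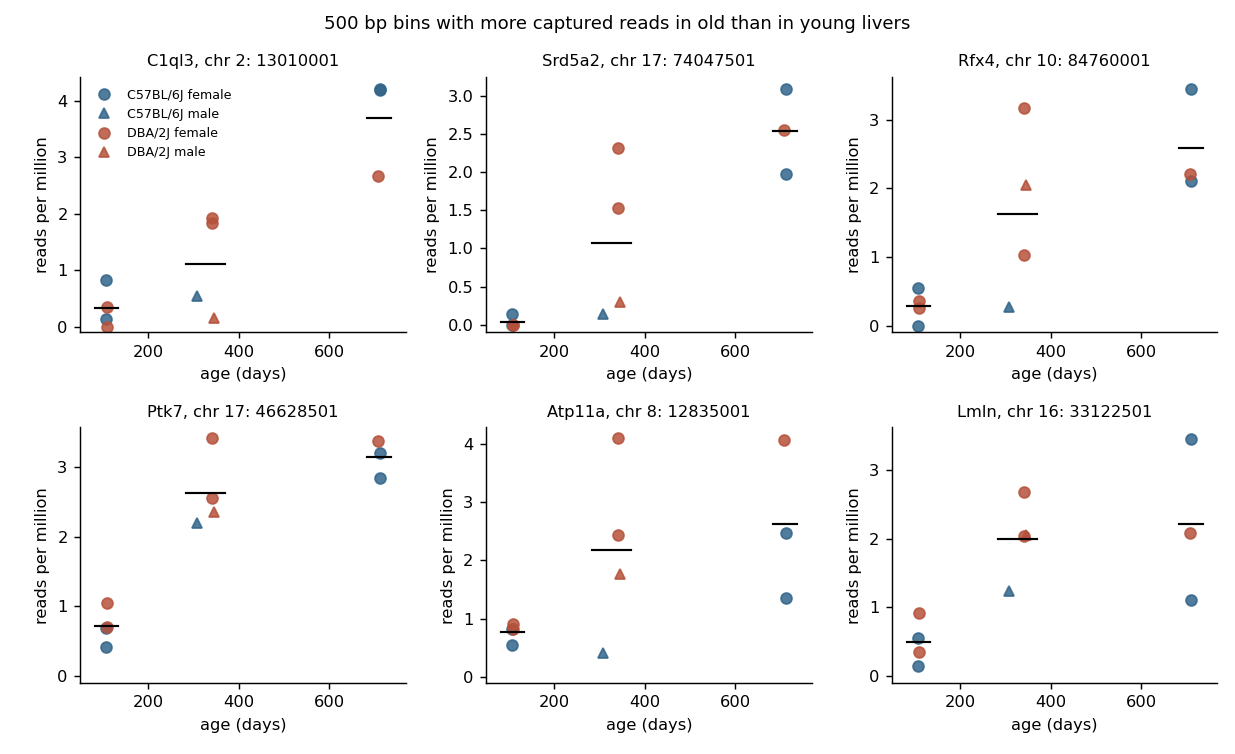
CPM (vertical axis) against age in days (horizontal axis) in 6 bins that were higher in old than in young livers, 1 point per library. Colour gives the strain, triangles are males, and black bars are class means. In the C1ql3 bin the mean rose from 0.331 in young to 3.69 in old livers.

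Over promoters, Srd5a2 rose by 2.38 log2 (SE 0.319, adjusted p = 7.1e-06), C1ql3 by 2.57 log2 (SE 0.394, adjusted p = 1.2e-04) and Ptk7 by 1.40 log2 (SE 0.242, adjusted p = 0.00125) in old livers, and none of the 12130 promoters fell past the threshold of edgeR. The promoter of Alb, the gene of serum albumin, had a log2 change of -0.22 (SE 0.545, adjusted p = 0.989). The clustered protocadherins, neuronal cell surface proteins, shifted upwards as a group. Of 55 measured members 46 had positive values, with a median of 0.20 log2 and an adjusted p of 5.1e-07 by camera. With an estimated correlation the p was 0.0762 (adjusted p = 0.345). No member passed over all genes, and Pcdha9 (0.68 log2, SE 0.193) was 1 member that passed when p was adjusted over the list alone; Pcdhga6 had 0.75, Pcdhb8 0.66 and Pcdhb18 0.49 log2.

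The list of lipid, cholesterol and bile acid metabolism shifted downwards, with 14 of 20 measured members negative, a median of -0.41 log2 and an adjusted p of 0.0192 by camera. With an estimated correlation the p was 0.0162 (adjusted p = 0.259). No member passed over all genes or adjusted over the list alone. Among the members with the smallest p were Acaca, the first enzyme of fatty acid synthesis (-1.04 log2, SE 0.376), the fatty acid carrier Fabp4 (-0.86) and the cholesterol acyltransferase Lcat (-0.40).

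The other 14 lists were not called in old against young livers, and no member of any of them passed over all genes or adjusted over the list alone. The developmental transcription factors, targets of polycomb repression, had 15 of 184 members measured (adjusted p = 0.835), among them Hoxa6 (0.88 log2) and Hoxa5 (0.41). Imprinted genes had 33 measured (adjusted p = 0.767; Rtl1 0.63 log2, Phlda2 -0.56). Hepatocyte proteins had 29 measured (adjusted p = 0.835), with a median of -0.14 log2 although camera gave the direction as up. Xenobiotic metabolism had 18 measured members, 11 of them negative (adjusted p = 0.200; Gstm6 -0.98 log2, Gstm4 -0.95). Polycomb and DNA methylation enzymes had 16, 11 of them negative (adjusted p = 0.200), among them Dnmt3a, a de novo DNA methyltransferase (-1.31 log2, SE 0.424), and Uhrf1, which recruits the maintenance methyltransferase Dnmt1 (-1.68, SE 0.603).

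Insulin and growth signalling had 13 measured promoters (adjusted p = 0.639; Akt1 -1.34 log2) and the circadian clock 5 (adjusted p = 0.504; Cry1 -0.85). Senescence genes had 15 (adjusted p = 0.871; E2f2 -0.59), with a camera direction up beside a median of -0.02, and tumour suppressors had 15 (adjusted p = 0.835; Dlc1 -0.62). The major histocompatibility complex had 16 (adjusted p = 0.835; H2-Ke6 -0.48) and the major urinary proteins 2 (adjusted p = 0.835; Mup21 -0.30), where the direction was again up beside a median of -0.03. Markers of other liver cells showed no group shift past the threshold. Lymphocyte markers had 27 measured (adjusted p = 0.835; Cd3e 0.38), Kupffer and myeloid markers 22 (adjusted p = 0.835; Tyrobp -0.85, Aif1 1.12), and endothelial, stellate and bile duct markers 19 (adjusted p = 0.871; Des 0.33, Lrat 0.70).

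Mid livers were compared with young ones as the intermediate step of age. The sex term takes up the males of this class, so the mid level of the fit comes from the 2 DBA/2J mid females alone. Srd5a2 had 34 reads over the 4 mid libraries in the bin at its transcription start, beside 1 read in young, a ratio of 34.6 with a counting interval from 5.802 to 1406 (edgeR adjusted p = 0.00214). The 2 DBA/2J mid females held 19 and 12 of these reads and the males 2 and 1, and the C1ql3 bin had 15 and 15 reads in these females and 1 and 4 in the males. Ptk7 rose by 4.01 log2 (SE 0.795, adjusted p = 0.0209) in the bin at 46629001 to 46629500, and C1ql3 by 2.94 log2 (SE 0.585, adjusted p = 0.0209). Adgrg6, an adhesion receptor, rose by 2.15 log2 (SE 0.434, adjusted p = 0.0271) upstream of its start on chromosome 10 (14547501 to 14548000). Mecr, a reductase of mitochondrial fatty acid synthesis, rose by 1.93 log2 (SE 0.399, adjusted p = 0.0463) in a coding exon on chromosome 4 (131861501 to 131862000). In other settings Mecr lost the call in 14 of 21, C1ql3 in 11 of 20 and Adgrg6 in 11 of 22.

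Exon bins of abundant liver genes fell in this fit, and the low values stood in the 2 DBA/2J mid females. Apoa1, the main protein of high-density lipoprotein, fell by 4.78 log2 (SE 0.580, adjusted p = 1.0e-10) on chromosome 9 (46230001 to 46230500), and Apoe, a ligand of lipoprotein receptors, by 3.00 log2 (SE 0.398, adjusted p = 1.3e-08) on chromosome 7 (19696001 to 19696500). Hp, which encodes haptoglobin, fell by 2.07 log2 (SE 0.370, adjusted p = 0.00214) on chromosome 8 (109575501 to 109576000). Fam169b fell by 2.30 log2 (SE 0.455, adjusted p = 0.0209) in an intron on chromosome 7 (68318501 to 68319000), with an adjusted p of 0.118 after the CpG offset. The C57BL/6J mid library was not lower than young C57BL/6J livers in the Apoe bin (1.92 against a mean of 1.31 CPM) or the Hp bin (3.70 against 3.46), and had 0.686 against 0.764 in the Apoa1 bin. The bins also differed within DBA/2J. The Apoa1 bin had 2 and 1 reads in the DBA/2J mid females and 23 in the DBA/2J mid male, beside 39 and 48 in the DBA/2J young females. Summed exon bins of Alb had 2.44 and 4.86 CPM in the DBA/2J mid females and 15.8 in the male.

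In total 7 bins were higher and 7 lower in mid livers. The 5 others were 3 further Apoe bins, a further Srd5a2 bin (3.06 log2, adjusted p = 0.0154) and an intergenic bin on chromosome 6 (128644501 to 128645000, 3.39 log2, adjusted p = 0.0271). The Srd5a2 bin lost the call in 10 of 22 other settings and the intergenic bin in 14 of 21. The comparison depends on the sex term, because the only males were in this class: without that term no bin of these 14 passed, and 1 other did. With the term the change was not measured across strains, because no C57BL/6J mid female was present. With females alone 14 bins passed, 12 of them shared. In bins outside exons no bin passed the edgeR threshold, and 17671 of 357194 had an unadjusted p under 0.05, no more than chance gives.

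**Figure D3:**
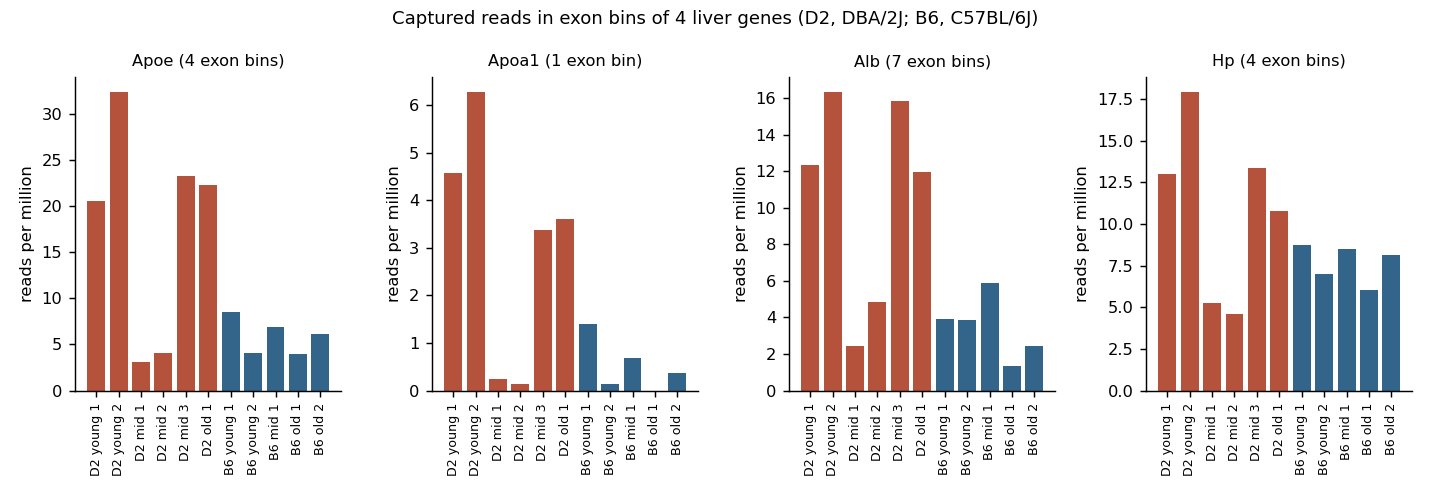
Captured CPM (vertical axis) summed over exon bins of Apoe, Apoa1, Alb and Hp, 1 bar per library (horizontal axis), coloured by strain. Among DBA/2J mid libraries the Apoe sum was 3.05, 4.09 and 23.3.

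The strains differed at many more bins than the ages. DBA/2J livers were higher in 3684 bins and lower in 7448, together 2.39 percent of the bins tested, with a median absolute change of 1.73 log2 among them. Among named bins with reads in every library, the bin in an intron of Gm45844 on chromosome 7 (7277501 to 7278000) had 1.13 ± 0.440 CPM in C57BL/6J (SD, n = 5) and 9.39 ± 2.04 in DBA/2J (SD, n = 6). Its log2 change was 3.13 (SE 0.282, edgeR adjusted p = 1.2e-24). The noncoding RNA gene E330020D12Rik was higher by 2.34 log2 (chromosome 1, 153413501 to 153414000, adjusted p = 1.9e-15) and Nlrp14, a NOD-like receptor gene, by 3.12 log2 (chromosome 7, 107179501 to 107180000, adjusted p = 5.0e-13). Alad, an enzyme of heme synthesis, was higher by 2.25 log2 (SE 0.282, adjusted p = 1.7e-12) in a coding exon on chromosome 4 (62510501 to 62511000).

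Apoe was higher in DBA/2J by 2.01 log2 (SE 0.248, adjusted p = 6.1e-13) in a coding exon (19696501 to 19697000), with 7.27 ± 4.68 against 2.404 ± 0.782 CPM. These means hold all libraries, but the log2 change does not draw on the DBA/2J mid females, which the mid term takes up. Their summed Apoe exon bins had 3.05 and 4.09 CPM, beside 3.96 to 8.48 in C57BL/6J libraries. Hdc, which makes histamine, was higher by 2.07 log2 (SE 0.273) and Ddx39b, an RNA helicase, by 1.93 log2 (SE 0.256). Gm20388 (3.02 log2), Fez2 (2.37), the immune receptor gene Cd101 (2.35), Rab6b (2.59), which encodes a small GTPase of vesicle traffic, and the noncoding 9530026P05Rik (3.54) completed the 12 named bins that were higher. Their adjusted p lay at or under 4.5e-11.

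Tmem267 was lower in DBA/2J by 3.62 log2 (SE 0.301, adjusted p = 4.3e-29) in a 5 prime UTR on chromosome 13 (119488501 to 119489000, 46 CpGs), with 14.5 ± 3.93 CPM in C57BL/6J and 0.885 ± 0.654 in DBA/2J. Tmem125 was lower by -3.49 log2 (SE 0.292, adjusted p = 1.0e-28) upstream of its start on chromosome 4 (118548001 to 118548500). Sfi1, a centrosomal gene, was lower by -2.46 log2 (SE 0.251, adjusted p = 2.9e-19) in an intron on chromosome 11 (3192501 to 3193000), with 78.6 ± 6.80 against 13.9 ± 0.969 CPM. The other named bins that were lower lay in or near Tmcc1 (-3.62 log2), the mucin gene Muc3 (-4.15), the zinc finger genes Zfp951 (-3.38) and Zfp981 (-3.29), AC166360.3 (-3.35), the collagen gene Col19a1 (-3.09), Gm3455 (-3.22), the pancreatic protease gene Ctrc (-2.91) and Pgm5 (-2.98), with adjusted p at or under 2.6e-15.

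Bins that differed between strains clustered in the genome. On chromosome 4 from 112000001 to 113000000 all 39 tested bins passed, and on chromosome 12 from 115000001 to 116000000 28 of 30 did. Of 2254 megabases with 20 or more bins, 663 held none. Runs were counted with gaps of at most 1 bin. The longest run of bins past the threshold held 15 bins, all lower in DBA/2J, on chromosome 12 (88091501 to 88099500), followed by 14 bins, all higher, on chromosome 17 (30868501 to 30876500). Dnah8, an axonemal dynein gene, held 134 bins that were higher and none lower, and Btbd9 held 30, Alad 14 and Glp1r, the receptor of glucagon-like peptide 1, 14 in the same direction. Exon bins differed in 1.22 percent of cases, intron bins in 2.06 percent and bins outside genes in 3.66 percent. Among bins that differed, the direction varied with the CpG number: 35.7 percent of those with 3 to 5 CpGs were lower in DBA/2J, 88.1 percent of those with 16 to 20 and 85.9 percent of those with over 20. Over all bins the median strain change was 0.02 log2 both at 3 to 5 and at over 20 CpGs.

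**Figure D4:**
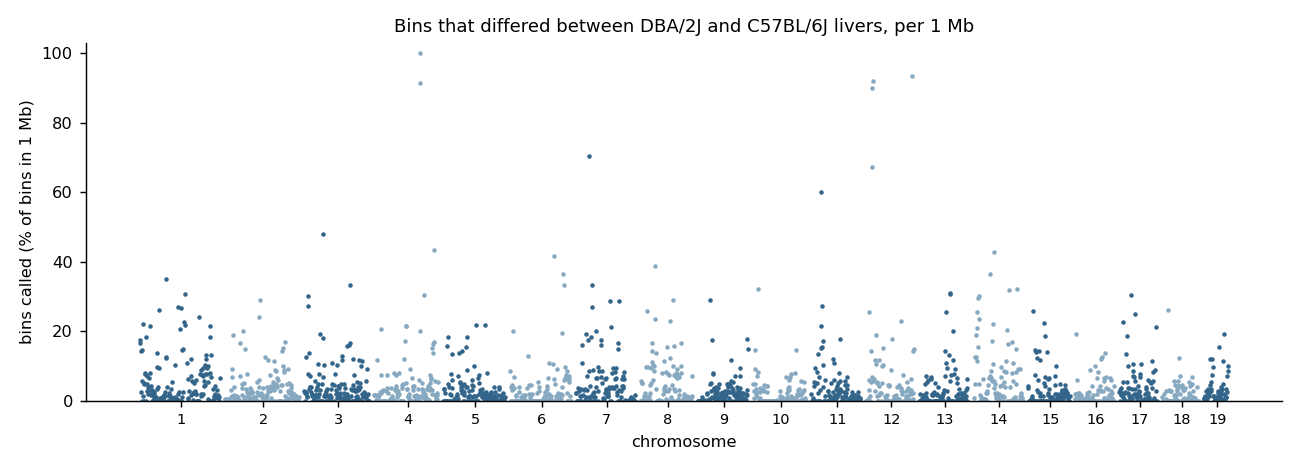
Share of tested bins that differed between DBA/2J and C57BL/6J (vertical axis, percent) in each megabase with 20 or more bins, along chromosomes 1 to 19 (horizontal axis). The highest point, at 100 percent, lies on chromosome 4.

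Sequence that is absent or differs in DBA/2J lowers its reads without any difference in methylation, and a duplicated copy might raise them. The counts do not separate these from a difference in methylation, in bins that were lower or higher. Of the bins past the threshold 734 had no read in any DBA/2J library and 7 none in any C57BL/6J library. Among those of the 11132 bins with at least 1 read in every library 3200 were higher and 4375 lower, 57.8 percent. With a mean of at least 20 reads 584 bins were higher and 434 lower.

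Over promoters, 124 genes were higher and 180 lower in DBA/2J. The hepatocyte list was shifted upwards, with 25 of 29 measured members positive, a median of 0.33 log2 and an adjusted p of 5.7e-09 by camera; with an estimated correlation the p was 0.00465 (adjusted p = 0.0744). Its members that were higher numbered 6 over all genes and 7 adjusted over the list alone, among them Apoa1 (2.402 log2, SE 0.320, adjusted p = 1.9e-07), Apoe (1.99, SE 0.292, adjusted p = 1.7e-06), Rbp4, the retinol carrier (3.01, SE 0.573, adjusted p = 2.7e-04), and Apoc1 (1.22, SE 0.298, adjusted p = 0.00869). For Apoe, summed exon bins had 3.05 and 4.09 CPM in the DBA/2J mid females and 3.96 to 8.48 in C57BL/6J libraries; the list was not tested by library. In bins outside exons the list was not called (adjusted p = 0.785).

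The clustered protocadherins were shifted downwards, with 46 of 55 negative, a median of -0.29 log2 and an adjusted p of 5.7e-09 by camera; with an estimated correlation the p was 0.0555 (adjusted p = 0.444). Of their promoters 5 were lower over all genes and 14 adjusted over the list alone. Pcdha4 fell by 0.81 log2 (SE 0.202), Pcdhgb1 by 0.98 (SE 0.244), Pcdhb21 by 0.89 (SE 0.244) and Pcdhb5 by 0.94 (SE 0.270), with adjusted p between 0.01002 and 0.0394.

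The other 14 lists were not called between strains. Xenobiotic metabolism (adjusted p = 0.781) had 1 member past the threshold, Ugt1a1, which conjugates bilirubin (-1.42 log2, SE 0.244, adjusted p = 4.5e-05), and imprinted genes (adjusted p = 0.807) had Ndn (-2.08, SE 0.323, adjusted p = 6.3e-06). Developmental transcription factors (adjusted p = 0.781) had Tbx3 (-1.72, SE 0.504, adjusted p = 0.0473), and 2 of them were lower adjusted over the list alone. Senescence genes (adjusted p = 0.781) had the chemokine gene Ccl5 (-1.001, SE 0.220). Tumour suppressors (adjusted p = 0.671) had Sfrp4 (-1.06, SE 0.254) and Cdh13 (-1.26, SE 0.322), and 3 were lower adjusted over the list alone. The major histocompatibility complex (adjusted p = 0.788) had H2-DMb1 lower (-4.29, SE 0.786), with 0.106 CPM in DBA/2J, and H2-D1 higher (0.68, SE 0.181).

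No member of the remaining lists passed over all genes or adjusted over the list alone between strains. Lipid metabolism and the major urinary proteins both had an adjusted p of 0.807. Insulin signalling, the circadian clock, lymphocyte markers, Kupffer and myeloid markers, and endothelial, stellate and bile duct markers each had 0.781, and polycomb and DNA methylation enzymes had 0.788. Among markers of other liver cells the values nearest to the threshold were those of Lck (0.73 log2, adjusted p = 0.0741) and Cd3e (-0.61, adjusted p = 0.123). For imprinted genes, tumour suppressors and xenobiotic metabolism the camera direction was down beside medians of 0.01, 0.02 and 0.01 log2. For endothelial, stellate and bile duct markers it was up beside a median of -0.02, and the lipid list had a positive median of 0.03 beside a mean of -0.01.

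Sex could be compared only in the mid class, which held the 2 males. In the fit Apoe was higher in males by 3.18 log2 (SE 0.511, edgeR adjusted p = 2.4e-04) at 19697001 to 19697500 and Apoa1 by 4.22 log2 (SE 0.699, adjusted p = 2.6e-04). The DBA/2J male had 39 and 23 reads in these bins, and the C57BL/6J male had 8 and 5. The DBA/2J male was not raised above other DBA/2J livers. Its summed Apoe exon bins had 23.3 CPM, beside 20.6, 32.4 and 22.3 in the DBA/2J young and old females. The low values were those of the DBA/2J mid females, 3.05 and 4.09. Cap2, an actin regulator, rose by 2.99 log2 (SE 0.502, adjusted p = 3.2e-04) on chromosome 13 (46531001 to 46531500), from 1.53 ± 0.991 CPM in females (SD, n = 9) to 4.61 ± 0.319 in males (SD, n = 2). Kntc1 (1.89 log2, adjusted p = 0.0446) and Tmem132c (2.03, adjusted p = 0.0447) were also higher, and lost the call in 11 and 12 of 22 other settings. The membrane repair gene Myof fell by 3.11 log2 (SE 0.612, adjusted p = 0.0229) and Rusc2 by 3.12 log2 (SE 0.617, adjusted p = 0.0231), while Sept7 (-4.92, adjusted p = 0.0600), Gm14319 (-2.40, adjusted p = 0.0682) and Zdhhc14 (-3.33, adjusted p = 0.0871) did not pass.

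In total 11 bins were higher and 5 lower in males. With library size alone the split was 8 higher and 6 lower, and with an offset by CpG number 16 higher and 14 lower. Outside exons it was 1 higher and 4 lower, without DBA/2J mid replicate 1 it was 0 and 3, and in DBA/2J alone 25 and 3. Over all bins the median sex change went from -0.08 log2 at 3 to 5 CpGs to 0.52 at over 20. In bins with over 20 CpGs the relative mean count was 2.16 and 1.90 in the males and 1.46 and 1.48 in the mid females. The remaining 9 bins past the threshold were 3 of Apoe, 1 each of Cap2, Ptgfrn and Myof, and 3 intergenic bins, of which the largest drop was -2.70 log2 (SE 0.465, adjusted p = 6.5e-04) on chromosome 3 (94682501 to 94683000). The Ptgfrn bin lost the call in 12 of 21 other settings. The labels of sex could not be checked on sex chromosomes, which had no bins.

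The change with age was compared between strains as a difference of slopes. It was lower in DBA/2J in 4 bins and higher in none; 39420 bins had an unadjusted edgeR p under 0.05. In a coding exon of Tmem267 on chromosome 13 (119609001 to 119609500) the mean fell from 8.27 CPM in young DBA/2J to 2.09 in the old library, and was 4.23 in young and 8.88 in old C57BL/6J livers. The difference of slopes was -0.50 log2 per 100 days (SE 0.0891, adjusted p = 0.00737). The next bin of Tmem267 (119609501 to 119610000) had -0.38 (SE 0.0750, adjusted p = 0.0481). Kmt5c, a histone H4 lysine methyltransferase, had -0.56 (SE 0.103, adjusted p = 0.0114) in a coding exon on chromosome 7 (4746001 to 4746500). Stra8, a gene of meiotic entry, had -0.49 (SE 0.0924, adjusted p = 0.0135) in a 5 prime UTR on chromosome 6 (34921001 to 34921500). In 15 other settings the first Tmem267 bin lost the call in 6, the second in 9, and Kmt5c and Stra8 each in 7.

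Jak3 (-0.47, adjusted p = 0.0566) and Mob3c (-0.45, adjusted p = 0.0712) did not pass, nor did bins with a higher slope in DBA/2J, in Kitl (0.58, adjusted p = 0.0566), Sfi1 (0.39, adjusted p = 0.101), Cd8a (0.60, adjusted p = 0.101), Cnot3 (0.68, adjusted p = 0.101) and Urb1 (0.54, adjusted p = 0.118). The DBA/2J slope rested on a single old library, and without it none of the 4 bins passed while 43 others did. With an offset by CpG number 9 bins passed, 6 higher and 3 lower, of which 1 was among the 4.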

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

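The tests on exon bins of Apoe, Apoa1 and Alb were chosen after the result was seen, and the other predictions were written before their values were computed, those on genes with all bins higher after the numbers of such bins had been seen. A test of the exon bins by the sex term was dropped because the male whose counts prompted it also fixed its outcome. An earlier test of the exon bins, which grouped 4 DBA/2J libraries by their own counts and left the question open, was dropped because that grouping came from the outcome. A test of the bins higher in DBA/2J against other splits was dropped because the split it was set against was nearly the strains reversed. Tests planned for the developmental transcription factor list were dropped because that list was not called.

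Single libraries lay far from the rest of their group in 7 of 143 groups tested, where chance gives about 1 in 20. Igfbp7 had 17.6 CPM in C57BL/6J young replicate 2 and between 0.974 and 1.44 in the other young libraries. The bin at the start of Srd5a2 had 0.139 in C57BL/6J young replicate 1 and 0 in the other young libraries, which is a single read. Myof had 4.35 (37936501 to 37937000) and 4.48 (37936001 to 37936500) in DBA/2J mid replicate 2, with at most 2.06 and 2.68 in the other females. Kitl had 3.599 in the old DBA/2J library and at most 1.53 in the other DBA/2J libraries. Apoe had 5.72 (19697001 to 19697500) and 3.52 (19697501 to 19698000) in the DBA/2J mid male, with at most 1.10 and 0.511 in the other mid libraries.

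The age slope differed between strains in 4 bins, by -0.50 and -0.38 log2 per 100 days in Tmem267, -0.56 in Kmt5c and -0.49 in Stra8, and other splits below show that chance cannot be excluded for them.

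Exon bins of Apoe, Apoa1 and Alb had 5.73 and 9.08 CPM in the DBA/2J mid females and 42.5 in the DBA/2J mid male, a ratio of 5.77 with a counting interval from 4.65 to 7.21. The DBA/2J young and old females had 37.5, 55.0 and 37.9, at least 0.883 of the male. The C57BL/6J male lay within the range of C57BL/6J females (13.4 against 5.32 to 13.8). The DBA/2J values met the prediction made for no sex difference of the same size at every age. That prediction took females to be alike at all ages. No young or old male was present, so a fall at the mid age together with a constant sex difference was not excluded, and the question stays open. Reads derived from transcripts could raise exon bins in the male: over 25 other hepatocyte genes the log2 ratio of the male to the mid females was higher in exon than in non-exon bins by a median of 0.29, which decides nothing, while in Alb it was 2.09 in exon bins and 2.08 in the 1 non-exon bin. The exon comparison did not adjust for CpG number. In bins with over 20 CpGs the relative mean count was 1.90 in the male and 1.46 and 1.48 in these females. A difference that belongs to the 2 mid females, and an effect of sex at the mid age alone, were not tested.

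The genes with at least 10 bins past the threshold, all higher in DBA/2J, were Dnah8, Btbd9, Alad and Glp1r. A duplicated copy in DBA/2J might give a doubling, and the median over all 540 bins of these genes was 0.80 log2 with 88.3 percent positive, which leaves it open. By gene the median was 0.88 in Dnah8 (286 of 289 bins positive), 0.96 in Glp1r, 0.41 in Btbd9 and 1.95 in Alad, and Dnah8 taken alone, a choice made after its values were seen, had what a doubling predicts. The SD of the changes over their median standard error was 1.92 for all bins together, which also holds differences between genes, and within genes it was 0.796 in Alad, 1.34 in Dnah8, 1.93 in Btbd9 and 2.03 in Glp1r. Changes that vary from bin to bin therefore stay open for these genes as a set.

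More bins were lower than higher in DBA/2J. Loss of DBA/2J reads against the C57BL/6J assembly was not decided: in a new fit of bins with at least 1 read in every library 58.1 percent of the 6415 past the threshold were lower, but this filter itself removes bins without DBA/2J reads. The variance of the bins per megabase was 14.9 times its mean, as sequence differences in blocks predict, and methylation differences in blocks were not tested apart from them.

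The libraries were also split in other ways, and each number of splits given here includes the real split. For old against young 3 of 35 splits gave as many bins (real 11, highest other 84), and for mid against young 3 of 35 did (real 14, highest other 56), so chance cannot be excluded; the splits with many more bins point to a structure of the samples. For the interaction 19 of 40 splits gave as many (real 4, highest other 3201), with the same reading. For the lists of old against young 12 of 35 gave as many (real 2, highest other 3) and for the lists of the strains 17 of 40 (real 2, highest other 3), so chance cannot be excluded. For the strains 1 of 60, the real one, gave as many bins (real 11134 with the dispersion trend held, highest other 5319). The highest other split was nearly the strains reversed. Only 60 of the possible splits were drawn, so chance is unlikely for the number of bins but not fully excluded.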

How the results depend on the processing

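Settings added after the data were seen are named in the methods part; where no cause is given, the cause was not tested. Chance gives a p under 0.05 in 5 percent of the bins tested. Named strain bins kept direction and call in 533 of 535 values, and those of old against young in 148 of 254, with 105 no longer past the threshold and Igfbp7 reversed: leaving out each library gave -2.21 (without old DBA/2J) to 0.74 (without C57BL/6J young replicate 2).

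Old against young had 11 bins, and 7 with library size alone, 6 without the sex term, 6 with age in days, 3 with at least 1 read in every library, 3 outside exons and 2 with the DESeq2 Wald test. It had 0 by edgeR with a mean of at least 20 reads (4876 with p under 0.05), 0 by edgeR in C57BL/6J alone (27250) and 0 by limma on the score (25831). Leaving out each library gave 6 to 15, with 6 without DBA/2J young replicate 1 or either old C57BL/6J library and 7 without any one DBA/2J mid library. Without the old DBA/2J library 14 passed, of which 4 were among the 11.

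Mid against young had 14 bins, and 3 with a mean of at least 20 reads, 1 without the sex term, 7 with at least 1 read in every library, 0 by edgeR outside exons (17671 with p under 0.05), 49 with the score, none of them shared, and 2 with the DESeq2 Wald test. Leaving out each library gave 3 (DBA/2J mid replicate 1) to 26 (C57BL/6J young replicate 2), with 6 and 7 without the DBA/2J young replicates 1 and 2, 7 without the old DBA/2J library and 9 without C57BL/6J old replicate 2.

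The strains had 11132 bins, and 1018 with a mean of at least 20 reads, where 42.6 percent were lower and fewer bins were tested, 6415 in a new fit of bins with at least 1 read in every library, 4387 with the score and 6253 with the DESeq2 Wald test. Leaving out each library gave 7407 (C57BL/6J mid male) to 12146.

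Sex had 16 bins, and 8 with a mean of at least 20 reads, 30 with the CpG offset, 28 in DBA/2J alone, 5 outside exons, 9 with 1 kb bins, 42 with the score, none of them shared, and 2 with the DESeq2 Wald test. Leaving out each library gave 3 (DBA/2J mid replicate 1) to 40 (old DBA/2J), with 10 without DBA/2J young replicate 1 or C57BL/6J young replicate 1, 8 without DBA/2J mid replicate 2 or the C57BL/6J male, 4 without the DBA/2J male and 25 without C57BL/6J young replicate 2.

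The interaction had 4 bins, and 7 with library size alone, 9 with the CpG offset, 0 by edgeR with age classes in females (37502 with p under 0.05) and 0 outside exons (27797). Leaving out each library gave 1 (DBA/2J young replicate 1, DBA/2J mid replicate 2 or C57BL/6J old replicate 2) to 71 (C57BL/6J young replicate 1), with 2 without C57BL/6J young replicate 2, 43 without old DBA/2J and 10 without C57BL/6J old replicate 1.

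Of the lists, 2 were called for old against young, and 1 with promoters of 1 kb, 0 outside exons, 0 with an estimated correlation, 0 with fry and 0 with the CpG offset and an estimated correlation. Leaving out each library gave 1 (DBA/2J young replicate 1 or C57BL/6J young replicate 1) to 3. For the strains 2 lists were called, and 0 outside exons, 0 with an estimated correlation, 1 with fry and 1 with the CpG offset and an estimated correlation, and each left-out library gave 2. With a median of 15 reads per bin, changes of 2-fold were mostly out of reach.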

Other observations

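All values in this part were computed after the results above were seen. Within the mid class, 4 of the 9 bins that were higher in old livers were lower in the 2 males than in the 2 females when adjusted over these 9, and none over all bins; both females were DBA/2J. C1ql3 had 1.87 CPM in mid females and 0.348 in mid males (-2.87 log2, SE 0.707), with an edgeR adjusted p of 4.4e-04 over the 9 bins higher in old livers and of 0.181 over all bins. Srd5a2 was lower by -3.09 log2 (SE 0.935) at its transcription start and by -2.18 log2 (SE 0.663) in its intron, each with an adjusted p of 0.00312 over the 9 bins, and Atp11a by -1.19 log2 (adjusted p = 0.0362). The other 5 did not pass: Rfx4 at 84760001 (-0.72 log2, adjusted p = 0.304) and 84759501 (-1.93, 0.0842), Ptk7 at 46628501 (-0.27, 0.529) and 46629001 (-0.79, 0.334) and Lmln (-0.38, 0.517).

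The lists were also tested for mid against young. Hepatocyte proteins (median -0.41 log2, adjusted p = 2.1e-09 by camera), lipid metabolism (-0.41, adjusted p = 0.00180) and imprinted genes (-0.24, adjusted p = 0.00803) were lower, and with an estimated correlation the adjusted p was 0.0553, 0.0553 and 0.520. With the CpG offset imprinted genes were not called (median -0.09 log2, adjusted p = 0.196), and the median change of all bins for mid against young went from 0.07 log2 at 3 to 5 CpGs to -0.23 at over 20. Over promoters, Apoa1 fell by 4.36 log2 (SE 0.556), Apoe by 3.35 (SE 0.497) and Apoc1 by 2.21 (SE 0.472) in the mid fit, and Srd5a2 rose by 2.14 (SE 0.372), Ptk7 by 1.53 (SE 0.281) and Adgrg6 by 1.62 (SE 0.332). The list and promoter values for mid livers come from the DBA/2J mid females, since the sex term takes up the males. In summed Apoe exon bins these females had 3.05 and 4.09 CPM, the DBA/2J mid male 23.3 and the C57BL/6J mid male 6.86.

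Genes with at least 10 bins past the threshold, all lower in DBA/2J, were Mroh2a, Gm49692, Cfap54, Gm7247 and Skint5. Over all their bins the median was -0.66 log2 in Mroh2a, -0.88 in Gm49692, -0.01 in Cfap54, -0.20 in Gm7247 and -5.83 in Skint5.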
